A study of Homo sapiens with 24 samples.

How the data were processed

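RNA from HEK293 cells was measured on Illumina HT-12 v4 expression BeadChips, which carry bead-bound probes for most human genes. The 24 arrays fall into 8 groups of 3: 4 lines with a doxycycline-inducible insert (empty vector or the G0, G1 or G2 form of APOL1), each without and with doxycycline (Dox). Total RNA was isolated with a QIAGEN RNeasy kit and labelled with biotin by a TargetAmp-Nano kit, per the labels' protocols. The labels say that the RNA came from 24 wells and do not say that the wells were separate experiments, so p-values here measure only the spread between these samples, which may be technical.

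The values analysed are the log2 expression values that the authors deposited, 1 per probe and array. GenomeStudio and RMA are named in the submitters' processing notes, without versions, and their order and settings are not given in the sources used here. The deposited values are on a log2 scale, as their range shows, and have array means between 5.12113 and 5.12195. The scaling that gave these nearly equal means is not stated, and no further normalization was applied. A table of scanner signals with detection p-values was not used here, because its 48 columns are named only by chip barcode and position and no label pairs them with a sample. Those columns name 2 chips of 12 arrays each, but the chip of a given sample is not known here, so chip could not enter any model. The test planned before the data were examined started from those signals with detection p-values. It was replaced by the same limma model on the deposited log2 values, with a filter on level in place of the filter on detection p-values.

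In all, 36 values on 16 arrays were exactly 0 on the log2 scale and were treated as missing. The deposited values have no detection p-values, so a background limit was taken from the values themselves. The mode of all values lay at 3.975 log2 units and the spread below it gave a standard deviation of 0.4129, which puts the 95th percentile of the background at 4.655 and the 99th at 4.936. Probes above 4.655 on at least 3 of the 24 arrays were kept, which left 20526 of 47317 probes. A level under this limit is called near background, and "at least N-fold" compares the brighter group's mean with the limit itself, for genes under it on every array of the dimmer group. Array annotation gave 1 gene symbol for 30111 probes, several for 8 and none for 17198. Of the probes with 1 symbol, 30090 were matched to a RefSeq gene table of GRCh38.p14, used for symbols alone, and 21 kept the annotation's symbol. Each gene was represented by its brightest kept probe with 1 symbol, which left 11865 genes, 3254 of them with other kept probes. The value of another probe is given where it had the opposite sign or a far smaller change than the named gene's brightest probe.

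Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with 1 mean per group and 1 shared estimate of the spread from all 24 arrays, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p of a gene below comes from limma. The comparisons were the Dox effect in each line, the differences between lines in that effect (interactions), the G1 and G2 lines against G0 with Dox, and the lines against each other without Dox. Here ± after a log2 change is the standard error of the fit, and ± after a group mean is the SD of 3 arrays. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists with at least 5 measured members within each comparison. The camera test was repeated with a correlation estimated for each list, and the limma rotation test fry was run as another alternative. Camera asks whether a list's genes moved more than the other genes did. Of 37 lists, 36 had a measured member. The lists cover mitochondrial complexes, ribosomes, import, dynamics and fuel use, the stress responses, lipid synthesis, glycolysis, signalling, inflammation, cell death, autophagy and lysosomes, the cell cycle, histones, ribosomes and their biogenesis, ion transport, the APOL family and markers of kidney, fibroblast, blood, vessel, carcinoma and neuronal cells.

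The groups, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. By that rule the text may name APOL1 to APOL6, the 8 largest rises and 8 largest falls of each Dox effect, the 6 largest each way of each interaction, the 5 largest each way of each direct comparison of lines, and the list members with the smallest p. Genes of a Dox effect or direct comparison had to be called and to show no overlap between the 3 arrays of one group and the 3 of the other. Uncharacterised symbols were skipped. To keep the account short, at most 3 genes each way are named for the interactions between APOL1 forms and at most 2 each way for those against the empty vector. List tests of the lines without Dox, and of each APOL1 line against the empty vector with or without Dox, were added after the data were seen, as were the level filter, the median centring and the quantile normalization of the deposited values.

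The model was tested on simulated data made from the 11864 genes with complete values. For the Dox effect in the empty vector line it recovered 36% of genes changed by 0.5 log2 units and 89% of those changed by 1, with 7 false calls among the unchanged genes. For the interaction between G2 and G0 it recovered 15% and 63%, with 4 false calls. In the G1 comparison a simulated list shifted by 0.3 had a camera adjusted p of 4e-22 and an unshifted list 0.446. The simulated genes varied independently, so this could not show how camera fares when the genes of a list are correlated. With 3 arrays per group, the number of arrays limits the precision of every value. Alternatives tried were no filter, a stricter level filter, quantile normalization, median centring, the mean of a gene's probes, exact 0 kept as 0, the replicate number as a block, a trended and robust prior, a fit to only the groups compared, a minimum fold of 1.5 and each array left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates and an independent set of arrays on another platform, which the design text mentions, were not analysed here.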

Results

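The study measured gene expression in HEK293 Tet-on cells, a line derived from human embryonic kidney in which doxycycline (Dox) switches on an inserted gene. The insert was an empty vector (EV) or 1 of 3 forms of APOL1, a gene for an apolipoprotein that kills trypanosomes. G0 is the reference form, and G1 and G2 are coding variants tied to a raised risk of kidney disease. Each of the 4 lines was profiled without and with Dox on 3 arrays, 24 in all, to ask which pathways respond to overexpression and which to the APOL1 form. Arrays are named by line, Dox state and number, as in G2 Dox 2. Between 35.8% and 37.0% of probes lay above the background limit on each array, and 11865 genes could be tested. The correlation between any 2 arrays across the tested genes was 0.905 to 0.994. The first principal component held 53.5% of the variance and set the Dox arrays of the G0, G1 and G2 lines (21.5 to 61.7) apart from all other arrays (-31.2 to -17.8). Among the 8 groups, G2 with Dox had the largest median gene SD, 0.219 log2 units against 0.115 to 0.165 in the others, and G2 Dox 2 lay apart from the other two arrays of that group.

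APOL1 itself could not be used to check the labels. Both of its probes stayed below the background limit on all 24 arrays, and it is not known here whether they lie within the inserted sequence. The first probe's difference with Dox was 0.26 in EV, 0.36 in G0, -0.44 in G1 and 0.57 in G2, and the second's was -0.25, 0.49, 0.16 and -0.23. In the 3 APOL1 lines the first probe's p was 0.1 by an exact permutation test, the smallest that 3 arrays against 3 allow. Of the related APOL2 to APOL6 genes, only APOL3 was tested. It was near background and rose by 0.55 ± 0.191 in G2 with Dox (adjusted p = 0.0162, at least 1.03-fold), a call that was lost without G2 Dox 1 (adjusted p = 0.0827) or G2 no Dox 3 (adjusted p = 0.117). Its other probes stayed below the limit on every array and gave -0.12 and -0.333 in G2. By the exact permutation test the p of the tested probe in G2 was 0.1.

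Dox alone, in the EV line, changed 3 of 11865 genes, 1 higher and 2 lower. HBD, a haemoglobin chain, rose by 1.29 ± 0.14 log2 units (adjusted p = 5.91e-05) from near background, to at least 1.19-fold its level without Dox. TNFRSF12A, a receptor of the tumour necrosis factor family, fell by 0.90 ± 0.134 and TNPO3, a nuclear import receptor, fell by 0.83 ± 0.126 (adjusted p = 0.00446 for both). Only HBD was called in a fit to the EV arrays alone and without EV no Dox 3, EV Dox 2 or EV Dox 3, and 15 genes were called without EV Dox 1. Here 974 genes had an unadjusted p under 0.05, where 593 would by chance, and the arrays of 12.1% of genes did not overlap, where chance gives 10%. The set test camera called 9 lists, among them the integrated stress response genes (median 0.128, 6 higher and 1 lower at an unadjusted p under 0.05) and the cytosolic ribosomal proteins (median 0.0845, or 0.0252 after quantile normalization, 4 higher and 0 lower at an unadjusted p under 0.05). No member of these 9 lists was called by limma over all genes, and none of the 9 calls held with an estimated correlation (the adjusted p ran from 0.365 to 0.618 with an estimated correlation).

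In the G0 line, Dox raised immediate early genes, which respond within minutes to signals, and lowered genes of the stress responses. FOS, a subunit of the AP-1 transcription factor, rose from 4.651 ± 0.331 to 8.835 ± 0.0857 (SD, n = 3), a log2 change of 4.18 ± 0.177 (adjusted p = 3.33e-13). Its mean without Dox was near background, so the size of this change is approximate. CXCL8, the chemokine interleukin-8, rose by 3.40 ± 0.185, MYCN by 3.28 ± 0.213 (1.13 at its other probe), EGR1 by 3.03 ± 0.133, CCN2 by 2.99 ± 0.152 and SGK1, a kinase of sodium transport, by 2.89 ± 0.184. PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, fell from 10.4 ± 0.253 to 7.181 ± 0.275, by 3.22 ± 0.201 (adjusted p = 8.84e-11, with -2.04 and -1.3 at its other probes). The stress cytokine GDF15 fell by 2.78 ± 0.26, DDIT3, the stress transcription factor CHOP, fell by 2.57 ± 0.159, and TRIB3 fell by 2.55 ± 0.168. TERF1, a telomere protein, fell by 3.17 ± 0.203, with a smaller change of -0.347 at its other probe.

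Of 32 measured immediate early and AP-1 genes, 29 rose and 0 fell in G0 (30 and 0 adjusted over the list alone; median 1.27, camera adjusted p = 4.82e-18, and adjusted p = 0.0143 with an estimated correlation). Of 29 integrated stress response genes, targets of the transcription factor ATF4, 25 fell and 2 rose, the same numbers adjusted over the list alone (median -1.20, camera adjusted p = 4.09e-13). Of 24 unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, 22 fell and 0 rose, again the same adjusted over the list alone (median -1.11, camera adjusted p = 9.74e-13). Among these, the chaperone HSPA5 fell by 2.43 ± 0.184 and CRELD2 fell by 2.30 ± 0.192. Of 14 histone genes 11 rose and 1 fell, also adjusted over the list alone (median 1.08, camera adjusted p = 1.2e-06), with H2BC11 up by 2.76 ± 0.134 and H2AC18 up by 2.00 ± 0.171. Potassium and sodium transport genes rose in 8 of 14 cases with 0 falls (9 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 0.00324), ATP1B1, a sodium pump subunit, by 1.13 ± 0.11. These 5 lists held with an estimated correlation, at adjusted p from 0.0143 to 0.0414. Cytosolic aminoacyl-tRNA synthetases, which load amino acids on tRNA, fell in 13 of 16 cases and rose in 1, the same adjusted over the list alone (median -0.81, camera adjusted p = 8.51e-06), and lost the call at adjusted p = 0.0771 with an estimated correlation. NF-kB and inflammatory genes rose in 7 of 15 cases with 0 falls (8 and 0 adjusted over the list alone; median 0.52, camera adjusted p = 0.00324), with NFKBIA, the inhibitor of NF-kB, up by 1.98 ± 0.148, and lost the call at adjusted p = 0.0607 with an estimated correlation.

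In all, 5298 genes were called in G0 (44.7%), 2522 higher and 2776 lower, and 2997 of them changed by at least 1.5-fold. The 3 arrays with Dox did not overlap the 3 without for 56.7% of all tested genes. By the rule for naming, none of the genes named as the largest rises or falls of a Dox effect or a direct comparison of lines had overlapping arrays.

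In the G1 line, FOS rose by 4.44 ± 0.177 (adjusted p = 9.37e-14) from near background, to at least 19.1-fold its level without Dox. MYCN rose by 3.10 ± 0.213 (1.39 at its other probe), IER3 by 3.06 ± 0.219 and ZCCHC12 by 2.98 ± 0.145. KPNA4, a nuclear import receptor, rose from 8.798 ± 0.0375 to 11.53 ± 0.0786 (SD, n = 3), by 2.73 ± 0.126 (adjusted p = 1.02e-12). The splicing factor SRSF7 fell by 2.74 ± 0.16, INHBE fell by 2.66 ± 0.244 and the prolyl isomerase PPIB fell by 2.24 ± 0.178. TERF1 fell by 3.46 ± 0.203, with -0.364 at its other probe.

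Of the immediate early and AP-1 genes 30 rose and 0 fell in G1, also adjusted over the list alone (median 1.37, camera adjusted p = 4.92e-18), and this was the 1 list of the 13 called that held with an estimated correlation (adjusted p = 0.0411). Unfolded protein response genes fell in 17 of 24 cases with 0 rises, the same adjusted over the list alone (median -0.70, camera adjusted p = 1.25e-05, adjusted p = 0.205 with an estimated correlation). Integrated stress response genes fell in 20 and rose in 2 of 29 cases (22 and 2 adjusted over the list alone; median -0.77, camera adjusted p = 2.04e-05, adjusted p = 0.133 with an estimated correlation). PCK2 stood at -1.87 ± 0.201 (-0.893 and -0.965 at its other probes) and TRIB3 at -1.84 ± 0.168. Histone genes rose in 11 of 14 cases and fell in 2, also adjusted over the list alone (median 0.99, camera adjusted p = 4.62e-05, adjusted p = 0.0658 with an estimated correlation). Aminoacyl-tRNA synthetases fell in 12 of 16 cases with 0 rises (13 and 1 adjusted over the list alone; camera adjusted p = 0.00113, adjusted p = 0.234 with an estimated correlation). NF-kB and inflammatory genes rose in 9 of 15 cases, also adjusted over the list alone (camera adjusted p = 0.00347, adjusted p = 0.094 with an estimated correlation). Potassium and sodium transport genes rose in 8 of 14 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00347, adjusted p = 0.0782 with an estimated correlation).

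Several mitochondrial lists were lower with Dox in G1. Mitochondrial ribosomal protein genes fell in 36 of 71 cases and rose in 1 (36 and 2 adjusted over the list alone; median -0.28, camera adjusted p = 6.47e-05, adjusted p = 0.372 with an estimated correlation). MRPS11 stood at -1.49 ± 0.146 and MRPL40 at -1.23 ± 0.138. Complex I subunits of the respiratory chain fell in 11 of 37 cases with 0 rises (8 and 0 adjusted over the list alone; median -0.25, camera adjusted p = 0.017, adjusted p = 0.668 with an estimated correlation), NDUFA7 at -0.94 ± 0.131 among them. Fatty acid beta-oxidation genes fell in 10 of 21 cases and rose in 1, also adjusted over the list alone (median -0.38, camera adjusted p = 0.0252, adjusted p = 0.336 with an estimated correlation). CPT2, an enzyme of mitochondrial fatty acid oxidation, stood at -1.47 ± 0.133. Mitochondrial import genes fell in 12 of 27 cases and rose in 3, also adjusted over the list alone (median -0.19, camera adjusted p = 0.0325, adjusted p = 0.336 with an estimated correlation). Glycolysis genes rose in 9 of 20 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.28, camera adjusted p = 0.0421, adjusted p = 0.322 with an estimated correlation). The glucose transporter SLC2A3 rose by 1.36 ± 0.115. Heat shock genes rose in 9 of 20 cases with 0 falls, also adjusted over the list alone (median 0.27, camera adjusted p = 0.0485, adjusted p = 0.211 with an estimated correlation). Over all genes, 5691 were called in G1 (48%), 2793 higher and 2898 lower, and 3272 changed by at least 1.5-fold. The arrays did not overlap for 60.6% of genes.

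The G2 line gave the largest number of calls. FOS rose from 4.935 ± 0.229 to 9.485 ± 0.311 (SD, n = 3), by 4.55 ± 0.177 (adjusted p = 2.75e-14). CXCL8 rose by 4.08 ± 0.185, CCN2 by 3.66 ± 0.152, the small GTPase GEM by 3.46 ± 0.175 (2.98 and 1.08 at its other probes), the matrix protein CCN1 by 3.18 ± 0.192 and the transcription factor KLF4 by 3.13 ± 0.152. GDF15 dropped to near background, from 7.365 ± 0.32 to 4.178 ± 0.445, at least 6.54-fold lower (adjusted p = 1.13e-09). SRSF7 fell by 2.95 ± 0.16, ZMYM6 fell by 2.82 ± 0.16 and PIGM, an enzyme of GPI anchors, fell by 2.77 ± 0.168. TERF1 fell by 3.94 ± 0.203, with -0.45 at its other probe.

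Of the immediate early and AP-1 genes 30 of 32 rose and 0 fell in G2, also adjusted over the list alone (median 1.75, camera adjusted p = 1.26e-16), and of 14 histone genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; median 1.13, camera adjusted p = 1.94e-05). Both held with an estimated correlation (adjusted p = 0.0497 for each), the only 2 of 14 called lists that did. Unfolded protein response genes fell in 19 of 24 cases with 0 rises, also adjusted over the list alone (median -0.93, camera adjusted p = 8.48e-06, adjusted p = 0.115 with an estimated correlation). HSPA5 stood at -1.88 ± 0.184. Integrated stress response genes fell in 23 of 29 cases and rose in 3 (24 and 3 adjusted over the list alone; median -0.79, camera adjusted p = 2.58e-05, adjusted p = 0.113 with an estimated correlation). NUPR1 stood at -2.64 ± 0.187 and DDIT4 at -2.51 ± 0.176. Potassium and sodium transport genes rose in 9 of 14 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00231, adjusted p = 0.0503 with an estimated correlation). NF-kB and inflammatory genes rose in 9 of 15 cases and fell in 2 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.115 with an estimated correlation). Aminoacyl-tRNA synthetases fell in 10 of 16 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.00827, adjusted p = 0.291 with an estimated correlation).

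Ribosome biogenesis genes and MYC targets rose in 15 of 23 cases and fell in 1, also adjusted over the list alone (median 0.63, camera adjusted p = 0.000365, adjusted p = 0.0818 with an estimated correlation). NOLC1 rose by 1.48 ± 0.134. Cytosolic ribosomal protein genes rose in 44 of 65 cases and fell in 1 (45 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 1.7e-05, adjusted p = 0.607 with an estimated correlation), but their median was 0.00842 after quantile normalization of the deposited values. Glycolysis genes rose in 13 of 20 cases and fell in 1 (13 and 2 adjusted over the list alone; median 0.49, camera adjusted p = 0.000616, adjusted p = 0.0733 with an estimated correlation). PFKFB3, a regulator of glycolysis, rose by 1.92 ± 0.176. Heat shock genes rose in 12 of 20 cases and fell in 1 (12 and 2 adjusted over the list alone; median 0.49, or 0.296 after quantile normalization, camera adjusted p = 0.00231, adjusted p = 0.0503 with an estimated correlation), DNAJB1 by 1.15 ± 0.12. S phase genes rose in 17 of 31 cases and fell in 3, also adjusted over the list alone (median 0.36, or 0.216 after quantile normalization, camera adjusted p = 0.00827, adjusted p = 0.115 with an estimated correlation), the uracil glycosylase UNG by 1.43 ± 0.124 (1.18 and 0.0632 at its other probes).

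Mitochondrial ribosomal protein genes fell in 35 of 71 cases in G2 and rose in 11, also adjusted over the list alone (median -0.30, camera adjusted p = 0.0279, adjusted p = 0.734 with an estimated correlation). MRPS11 stood at -1.89 ± 0.146. Beta-oxidation genes fell in 12 of 21 cases and rose in 2, also adjusted over the list alone (median -0.57, camera adjusted p = 0.0224, adjusted p = 0.291 with an estimated correlation). CPT2 stood at -2.24 ± 0.133 and ACADM, the medium-chain dehydrogenase, at -1.03 ± 0.122. Complex I subunits fell in 12 of 37 cases and rose in 1, a list not called here (camera adjusted p = 0.13). G2 Dox 2 stood apart in these lists: the mitochondrial ribosomal median over EV without Dox was -0.347 there against -0.595 and -0.627 on the other two arrays, and the complex I median was -0.157 against -0.614 and -0.467. In total 6935 genes were called in G2 (58.4%), 3207 higher and 3728 lower, 4471 of them with a change of at least 1.5-fold, and the arrays did not overlap for 57.6% of genes. Centring each array on its median moved the median change of all genes from -0.0454 to 0.0931 and the share of higher calls from 46.2% to 58.0%. The lists named here kept their direction, with centred medians of -0.157 for the mitochondrial ribosomal proteins and -0.435 for beta-oxidation.

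**Figure D1:**
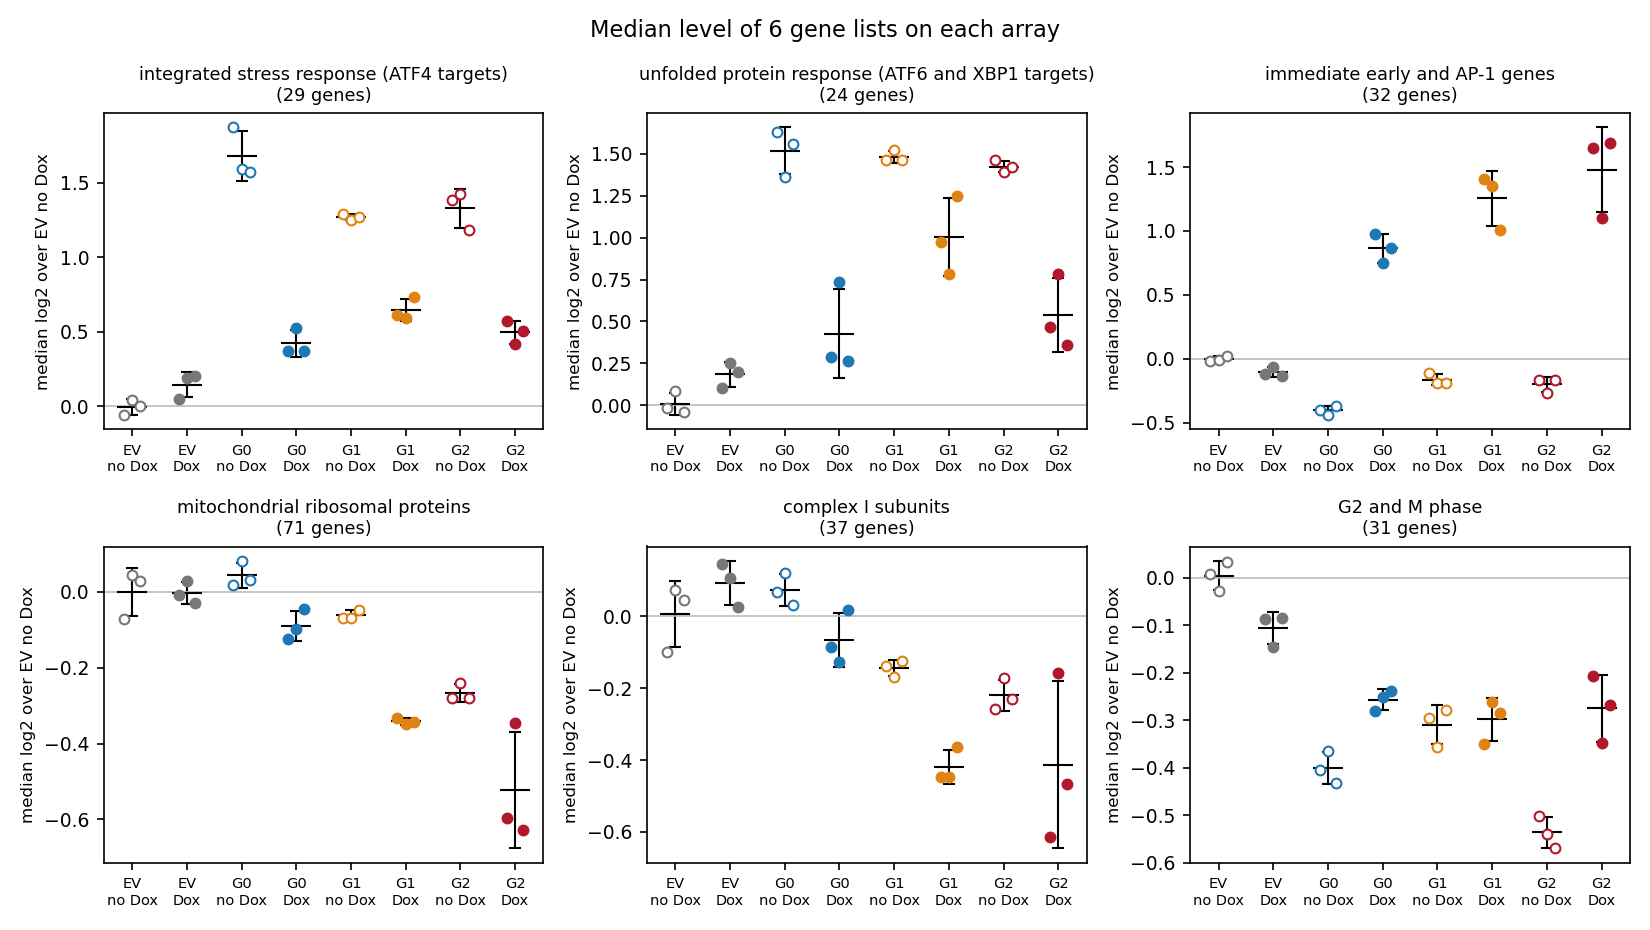
Each panel plots 1 gene list: each point is 1 array, its height the median over the list's genes of the log2 level over the EV mean without Dox, with open points without Dox, filled points with Dox, and bars for the mean and SD of 3 arrays. Integrated stress response genes stand at 1.68 ± 0.168 in G0 without Dox and 0.422 ± 0.0886 with Dox, and immediate early genes at -0.402 ± 0.0345 and 0.864 ± 0.113.

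The Dox effects of the 3 APOL1 lines resembled one another and not that of EV. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.818 (rho = 0.774) between G0 and G1, 0.838 (0.798) between G0 and G2 and 0.908 (0.883) between G1 and G2. Between EV and G0, G1 and G2, r was -0.0333, -0.146 and -0.149. G0 and G2 shared 1949 genes called higher and 2304 called lower, where independent lists would share 682 and 872, and 35 were called in opposite directions. For G0 and G1 the numbers were 1767 and 1998 (594 and 678 for independent lists, 26 opposite), and for G1 and G2 they were 2309 and 2592 (755 and 911, 11 opposite). The lines have separate control arrays. In all 3 lines, 1626 genes rose and 1910 fell, FOS, EGR1 and CXCL8 among the former and PCK2, HSPA5 and DDIT3 among the latter. Over these 3536 genes the median size of the log2 change was 0.722 in G0, 0.771 in G1, 0.967 in G2 and 0.115 in EV.

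Taking the Dox effect of EV away from that of each APOL1 line asks what the insert adds to Dox. FOS rose by 4.78 ± 0.25 more in G0 than in EV (adjusted p = 1.55e-11), where its own change was -0.60 (adjusted p = 0.462), and EGR1 rose by 3.72 ± 0.189 more. The mean of FOS in G0 without Dox was near background, so the size of its difference is approximate. PCK2 fell more in G0 than in EV, by -3.20 ± 0.285 (-2.05 and -1.14 at its other probes), and INHBE by -3.06 ± 0.345. In G1 the differences were 3.05 for EGR1, -3.28 for TERF1 (-0.189 at its other probe) and -3.00 for INHBE. That of FOS was at least 4.85, since FOS was near background in G1 without Dox. In G2 they were 5.15 for FOS, 4.12 for CXCL8, and -3.76 for TERF1 (-0.275 at its other probe). GDF15 was near background in G2 with Dox, and its difference was -2.95 or more in size. Immediate early genes rose more than in EV in 28, 29 and 29 of 32 cases in G0, G1 and G2 (29, 29 and 30 adjusted over the list alone), with medians of 1.27, 1.35 and 1.71, and these 3 calls held with an estimated correlation (adjusted p = 0.014, 0.0369 and 0.0472). Integrated stress response genes fell more than in EV in 24, 20 and 21 of 29 cases (25, 21 and 22 adjusted over the list alone; medians -1.33, -0.915 and -0.893), with adjusted p = 0.0111, 0.101 and 0.0738 with an estimated correlation. Unfolded protein response genes did so in 22, 17 and 21 of 24 cases (22, 18 and 21 adjusted over the list alone; medians -1.19, -0.77 and -1.04), with adjusted p = 0.014, 0.119 and 0.0903 with an estimated correlation. Histone genes rose more in 8, 10 and 8 of 14 cases (9, 10 and 8 adjusted over the list alone; medians 1.02, 0.879 and 1.01), with adjusted p = 0.014, 0.101 and 0.0671 with an estimated correlation. The Dox effect differed from that of EV for 3603 genes in G0 (1778 higher, 1825 lower), 4227 in G1 (2143 and 2084) and 5379 in G2 (2522 and 2857). These 3 comparisons share the EV arrays.

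**Figure D2:**
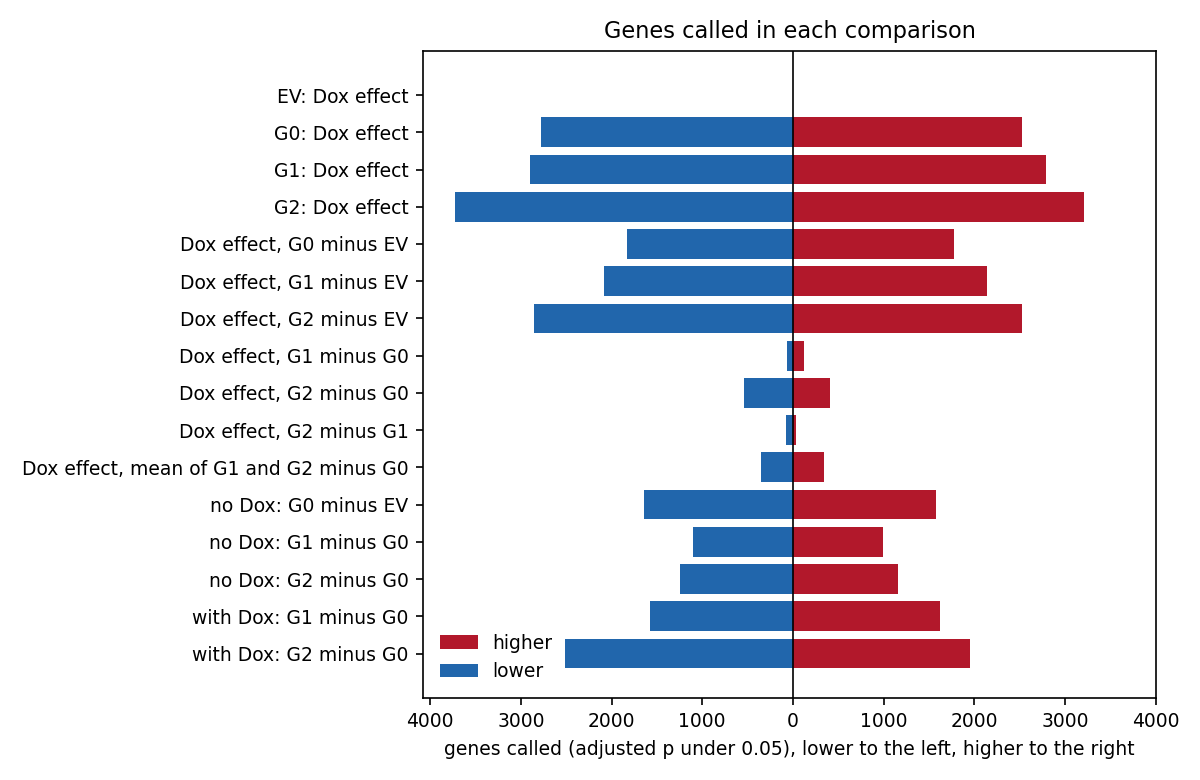
Bars show the number of genes called by limma in each comparison, higher to the right in red and lower to the left in blue, of 11865 tested. The Dox effect called 3 genes in EV and 5298, 5691 and 6935 in G0, G1 and G2, while its difference between G1 and G0 called 178 and that between G2 and G0 951. In fits to only the groups compared, these differences called 559 and 474 genes, in the reverse order.

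Between G1 and G0, genes of the stress responses differed in their response to Dox. HYOU1, a chaperone of the endoplasmic reticulum, changed by -2.08 in G0 and -0.475 in G1, a difference of 1.60 ± 0.257 (adjusted p = 0.00438). The glycine transporter SLC6A9 changed by -1.99 in G0 and -0.25 in G1 (difference 1.74 ± 0.212, adjusted p = 0.000216), and KPNA4 rose more in G1, by 1.93 ± 0.178 (adjusted p = 2.85e-06). The telomere protein TINF2 had a difference of -1.38 ± 0.285 and ZNF784 one of -1.29 ± 0.264. ZNF365 was called lower too (fitted -1.61 ± 0.297) but was near background in every group compared except G1 without Dox, so its size is not known. Integrated stress response genes fell less in G1 in 9 of 29 cases (14 adjusted over the list alone; median difference 0.521, camera adjusted p = 2.2e-11), and the call held at adjusted p = 0.0426 with an estimated correlation. Part of this was a lower start in G1: the mean difference from G0 over the 29 genes was -0.277 without Dox and 0.32 with Dox. Unfolded protein response genes fell less in 5 of 24 cases (11 adjusted over the list alone; median 0.49, camera adjusted p = 2.56e-07, adjusted p = 0.319 with an estimated correlation). Mitochondrial ribosomal proteins had a lower Dox effect in G1 in 2 of 71 cases, also adjusted over the list alone (median -0.166, camera adjusted p = 1.47e-05, adjusted p = 0.78 with an estimated correlation). For the aminoacyl-tRNA synthetases limma called 0 of 16 over all genes, with 5 at an unadjusted p under 0.05, all higher (4 adjusted over the list alone; median 0.221, camera adjusted p = 0.0331, adjusted p = 0.725 with an estimated correlation).

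The Dox effect differed between G1 and G0 for 178 genes, 117 higher and 61 lower in G1, and the higher share was 65.7% as deposited and 55.4% after median centring. The count was 37 without the level filter and 559 in a fit to the 4 groups compared. It was 52 without G0 no Dox 1, 74, 118 and 52 without G0 Dox 1, 2 and 3, 78 and 103 without G1 Dox 1 and 2, and 118, 60 and 50 without G1 no Dox 1, 2 and 3. TINF2 and ZNF784 lost their calls without the filter (adjusted p = 0.0542 for both), TINF2 also without G0 Dox 3 (0.0512), G1 Dox 1 (0.0508) or G1 no Dox 3 (0.0646), and ZNF784 without G0 no Dox 1 (0.0571), G1 no Dox 2 (0.0507) or G1 no Dox 3 (0.0543).

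Between G2 and G0, CCN1 rose by 1.58 in G0 and 3.18 in G2, a difference of 1.60 ± 0.272 (adjusted p = 0.00292). CCDC86, a nucleolar protein, rose by 0.62 and 2.17 (difference 1.55 ± 0.257, adjusted p = 0.00286), and GEM by 2.03 and 3.46 (1.43 ± 0.247, adjusted p = 0.003, with 1.09 and 0.382 at its other probes). ZBTB42 had a difference of -1.60 ± 0.268 and the homeobox gene HOXB5 one of -1.41 ± 0.25. XYLT1 was called lower (fitted -1.57 ± 0.298) but was near background in every group compared except G0 with Dox, so its size is not known. Ribosome biogenesis genes and MYC targets rose more in G2 in 9 of 23 cases (13 adjusted over the list alone; median difference 0.593, camera adjusted p = 4.04e-07), the only 1 of 8 called lists to hold with an estimated correlation (adjusted p = 0.0498). Its mean difference from G0 was -0.254 without Dox and 0.186 with Dox. Immediate early genes rose more in 4 of 32 cases (7 adjusted over the list alone; median 0.369, camera adjusted p = 0.000143, adjusted p = 0.458 with an estimated correlation). Glycolysis genes rose more in 3 of 20 cases and less in 1 (5 and 1 adjusted over the list alone; median 0.32, camera adjusted p = 0.00229, adjusted p = 0.179 with an estimated correlation). Their mean difference from G0 was -0.249 without Dox and 0.0494 with Dox. Heat shock genes rose more in 4 of 20 cases (5 adjusted over the list alone; median 0.258, or 0.118 after quantile normalization, camera adjusted p = 0.00265, adjusted p = 0.0837 with an estimated correlation). S phase genes did so in 1 of 31 cases, also adjusted over the list alone (median 0.207, camera adjusted p = 0.0206, adjusted p = 0.259 with an estimated correlation), with a mean difference from G0 of -0.128 without Dox and 0.0174 with Dox. Cytosolic ribosomal proteins rose more in 4 of 65 cases (14 adjusted over the list alone; median 0.298, camera adjusted p = 2.18e-08, adjusted p = 0.635 with an estimated correlation), with a median of 0.0102 after quantile normalization.

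Integrated stress response genes had a higher Dox effect in G2 than in G0 in 4 of 29 cases, also adjusted over the list alone (median 0.365, camera adjusted p = 0.000129, adjusted p = 0.254 with an estimated correlation). This difference lay in the arrays without Dox, where the mean of the list in G2 was below that in G0 (-0.346), while with Dox the means differed by -0.00266. For the unfolded protein response genes it was 1 of 24, also adjusted over the list alone (median 0.243, or 0.116 after quantile normalization, camera adjusted p = 0.0123, adjusted p = 0.621 with an estimated correlation). The Dox effect differed between G2 and G0 for 951 genes, 408 higher and 543 lower in G2, and the higher share was 42.9% as deposited and 64.7% after median centring. The count was 303 without the level filter and 474 in a fit to the 4 groups compared. It was 1711 without G2 Dox 2, 495 without G2 Dox 3, 334 and 609 without G2 no Dox 1 and 2, 372 without G0 no Dox 1, and 552, 532 and 633 without G0 Dox 1, 2 and 3.

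**Figure D3:**
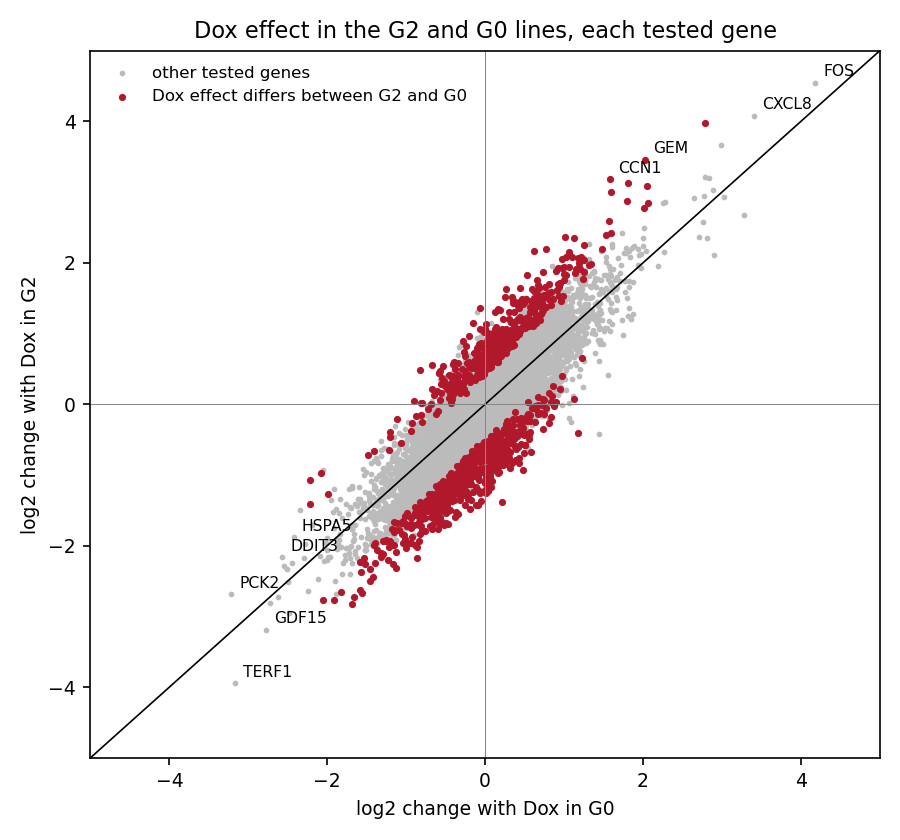
Each point is 1 of 11865 genes, with the log2 change with Dox in G0 on the horizontal axis and in G2 on the vertical axis, genes whose Dox effect differs between the lines in red and equal change on the diagonal. The changes correlate at r = 0.838 across genes, and 951 genes are red.

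Between G2 and G1, TNFRSF12A had a higher Dox effect in G2 by 1.65 ± 0.19 (adjusted p = 5.43e-05) and DUSP1, a phosphatase of MAP kinases, by 1.23 ± 0.222 (adjusted p = 0.0111). KPNA4 had a lower one, by -1.91 ± 0.178 (adjusted p = 3.36e-06), as did SKIDA1, by -1.41 ± 0.194 (adjusted p = 0.000502), and NUPR1, by -1.38 ± 0.264 (adjusted p = 0.0186, with -0.274 at its other probe). ZNF365 was called higher in G2 (fitted 1.26 ± 0.297, adjusted p = 0.0434), near background in every group compared except G1 without Dox, a call lost under several settings, among them no filter (adjusted p = 0.12). DUSP1 lost its call in a fit to the 4 groups compared (adjusted p = 0.0649), and NUPR1 with no filter (0.0541), in that fit (0.0615), with the mean of its probes (0.143) and without G1 Dox 1 (0.0501) or G1 Dox 3 (0.0525). Only 114 genes differed, 35 higher and 79 lower in G2, a higher share of 30.7% that became 71.1% of 190 genes after median centring, which moved the median of all genes from -0.0406 to 0.0728. Their number was 17 without the filter, 12 in a fit to the 4 groups compared, 205 with a trended and robust prior and 181 with a stricter filter. It was 567 without G2 Dox 2, 75 without G2 Dox 3, 37, 53 and 21 without G2 no Dox 1, 2 and 3, 34 and 26 without G1 Dox 1 and 3, and 34, 33 and 37 without G1 no Dox 1, 2 and 3. For ZNF365 the adjusted p was 0.0934 and 0.0725 without G1 Dox 1 and 2, 0.0727 without G2 Dox 1, 0.0888, 0.108 and 0.0634 without G1 no Dox 1, 2 and 3, and 0.0503, 0.0972 and 0.107 without G2 no Dox 1, 2 and 3.

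Both risk forms together, as the mean of the G1 and G2 effects, were set against G0. ZCCHC12 rose by 1.60 in G0, 2.98 in G1 and 3.01 in G2, a difference of 1.40 ± 0.178 (adjusted p = 0.000862). In G2 it started lower than in G0 without Dox, as given below, which enters this difference. HYOU1 fell less in the risk lines, with a difference of 1.36 ± 0.222 (adjusted p = 0.00427), and CCDC86 rose more, by 1.25 ± 0.222 (adjusted p = 0.00594). XYLT1 was called lower (fitted -1.38 ± 0.258, adjusted p = 0.00735) but was near background in all groups compared except G0 with Dox. The 28S ribosomal RNA gene RNA28SN5 had a lower effect, by -2.04 ± 0.576 (adjusted p = 0.0388, with -0.999 at its other probe), as had TMUB2, by -1.29 ± 0.36 (adjusted p = 0.0363, with 0.126 and -0.0452 at its other probes). The calls of RNA28SN5 and TMUB2 were lost with no filter (adjusted p = 0.0929 and 0.0885). For RNA28SN5 the adjusted p was 0.0745, 0.077 and 0.0733 without G0 no Dox 1, 2 and 3, 0.115, 0.0763 and 0.0515 without G0 Dox 1, 2 and 3, 0.0549 and 0.0537 without G1 Dox 1 and 3, 0.0563 and 0.0691 without G1 no Dox 2 and 3, 0.0678 and 0.05 without G2 no Dox 1 and 2, 0.0509 with the replicate number as a block and 0.0518 with the mean of its probes. For TMUB2 it was 0.13 and 0.0584 without G0 no Dox 1 and 2, 0.0773, 0.0741 and 0.0773 without G0 Dox 1, 2 and 3, 0.0515 without G1 Dox 2, 0.0556 and 0.063 without G1 no Dox 2 and 3, 0.0631 without G2 no Dox 1, and 0.0543 with the mean of its probes.

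The integrated stress response was the list with the lowest camera p. Of its 29 genes 8 had a higher Dox effect in the risk lines (14 adjusted over the list alone; median 0.403, camera adjusted p = 6.01e-09, adjusted p = 0.108 with an estimated correlation). CTH, an enzyme of cysteine synthesis, stood at 1.15 ± 0.226 (0.566 and 0.804 at its other probes) and the amino acid transporter chain SLC3A2 at 0.86 ± 0.155. Without Dox, CTH was lower in G2 than in G0, at -1.94 (-1.08 and -1.41 at its other probes), which enters its value. For the unfolded protein response it was 4 of 24 (9 adjusted over the list alone; median 0.444, camera adjusted p = 4.22e-05, adjusted p = 0.324 with an estimated correlation). PDIA4 stood at 0.83 ± 0.198. Ribosome biogenesis genes had a higher effect in 5 of 23 cases (9 adjusted over the list alone; median 0.343, or 0.225 after quantile normalization, camera adjusted p = 0.000329, adjusted p = 0.207 with an estimated correlation). ODC1 stood at 0.71 ± 0.137 and nucleolin, NCL, at 0.52 ± 0.119. Immediate early genes had a higher effect in 4 of 32 cases (6 adjusted over the list alone; median 0.251, camera adjusted p = 0.0182, adjusted p = 0.681 with an estimated correlation). CCN1 stood at 1.21 ± 0.235 and KLF4 at 0.93 ± 0.186. Aminoacyl-tRNA synthetases had one in 1 of 16 cases, GARS1 at 0.56 ± 0.159 (3 of 16 adjusted over the list alone; median 0.16, or 0.0898 after quantile normalization, camera adjusted p = 0.0436, adjusted p = 0.666 with an estimated correlation). Of 65 cytosolic ribosomal proteins limma called 0 over all genes and 0 adjusted over the list alone, with 13 higher and 2 lower at an unadjusted p under 0.05 (median 0.176, camera adjusted p = 0.000141, adjusted p = 0.827 with an estimated correlation, and a median of 0.00331 after quantile normalization). PDIA4 lost its call with no filter (adjusted p = 0.0578), without G0 no Dox 1 (0.0729) or 3 (0.0504) and without G0 Dox 1 (0.0599) or 3 (0.0515), and NCL with no filter (0.057) and without G0 no Dox 1 (0.0646) or G0 Dox 2 (0.0536). GARS1 lost it with no filter (0.0943), after quantile normalization (0.0623), without G0 no Dox 1 (0.141) or 2 (0.0544), without any of G0 Dox 1 to 3 (0.0826, 0.0651 and 0.0913), without G2 Dox 3 (0.054), without G1 no Dox 2 (0.0519) or 3 (0.0648) and without G2 no Dox 1 (0.0664) or 2 (0.0507).

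Mitochondrial ribosomal proteins had a lower Dox effect in the risk lines than in G0 in 7 of 71 cases, also adjusted over the list alone (median -0.164, camera adjusted p = 0.000701, adjusted p = 0.723 with an estimated correlation). MRPS25 stood at -0.90 ± 0.2 (adjusted p = 0.0167) and MRPL10 at -0.81 ± 0.147 (adjusted p = 0.00638), but the other probe of MRPL10 gave 0.438 and its call was lost with the mean of its probes (adjusted p = 0.644). The call of MRPS25 was lost without G0 no Dox 1 (adjusted p = 0.0659). Over 210 genes of 7 mitochondrial lists, 1 had a higher and 9 a lower effect in the risk lines, and the median difference was -0.0804. The lists differed: complex II to IV subunits, ATP synthase and the TCA cycle had medians of 0.0164, 0.0482 and 0.0454, which turned negative with quantile normalization, and only the mitochondrial ribosomal proteins were called. In all, 702 genes differed between the risk forms and G0, 345 higher and 357 lower, a higher share of 49.1% as deposited and 58% after median centring. The count was 136 without the level filter, 128 without G0 no Dox 1, 283, 242 and 272 without G0 Dox 1, 2 and 3, 1282 without G2 Dox 2, 458 and 416 without G1 no Dox 2 and 3, and 392 without G2 no Dox 1.

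With Dox in both, the risk lines were also compared with G0 directly, which includes any difference the lines had before. MAOA, monoamine oxidase A, was higher in G1 by 2.58 ± 0.201 (adjusted p = 2.2e-08), KPNA4 by 2.03 ± 0.126 and GOLGA8B by 2.18 ± 0.198. TMSB15A was lower in G1, at -2.06 ± 0.131 (adjusted p = 8.5e-10), as were the pore-forming protein gene GSDMD at -2.03 ± 0.196 and the DNA repair gene MGMT at -1.91 ± 0.195. In G2 the protocadherin PCDH19 was higher by 2.45 ± 0.205 (adjusted p = 7.28e-08), MAOA by 2.13 ± 0.201 and CCN1 by 1.88 ± 0.192. HAND1 was lower in G2 at -1.91 ± 0.164, the mitochondrial dicarboxylate carrier SLC25A10 at -1.85 ± 0.224 and MGMT at -1.85 ± 0.195. Without Dox, MAOA was already higher than in G0 in both risk lines, PCDH19 in G2, and TMSB15A already lower in G1, as given below. G1 differed from G0 in 3207 genes, 1626 higher and 1581 lower, 1393 of them by at least 1.5-fold, and the higher share was 50.7% as deposited and 39.6% after median centring. G2 differed in 4455, 1947 higher and 2508 lower, 2240 of them by at least 1.5-fold, and in 2902 in a fit to the G2 and G0 arrays with Dox.

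Without Dox, the 3 APOL1 lines already differed from EV, most of all in the stress response genes. HSPA5 stood at 10.58 ± 0.195 in G0 and 7.077 ± 0.141 in EV (SD, n = 3), higher by 3.51 ± 0.184 (adjusted p = 1.05e-11), and DDIT3 was higher by 3.31 ± 0.159, TRIB3 by 3.07 ± 0.168 and HYOU1 by 2.83 ± 0.181. MAOA was lower in G0 at -2.34 ± 0.201, the muscle ankyrin repeat gene ANKRD1 at -2.26 ± 0.158, TNFRSF12A at -2.05 ± 0.134 and CCN2 at -1.91 ± 0.152. Of 29 integrated stress response genes 27 were higher and 0 lower in G0, also adjusted over the list alone (median 1.64, camera adjusted p = 3.49e-33). Unfolded protein response genes were higher in 22 of 24 cases and lower in 0, also adjusted over the list alone (median 1.45, camera adjusted p = 8.4e-27), and G2 and M phase genes lower in 15 of 31 and higher in 0 (18 and 0 adjusted over the list alone; median -0.33, camera adjusted p = 2.87e-08). These 3 lists held with an estimated correlation (adjusted p = 0.000176, 0.00126 and 0.000907). HSPA5 was higher than in EV by 3.50 in G1 and 3.11 in G2, and DDIT3 by 2.49 and 2.48. The same 3 lists were called and held with an estimated correlation in these comparisons too, which share the EV arrays: 26 of 29 stress response genes were higher in G1 and 27 in G2 (29 and 28 adjusted over the list alone), 21 and 20 of 24 unfolded protein response genes were higher (23 and 21 adjusted over the list alone), and 16 and 23 of 31 G2 and M phase genes were lower (18 and 27 adjusted over the list alone). In G2 against EV, 4 of the 16 called lists held, these 3 among them. Over all genes 3218 differed between G0 and EV, 1576 higher and 1642 lower, 1503 of them by at least 1.5-fold.

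The risk lines also differed from G0 before induction. MAOA was higher by 2.33 ± 0.201 in G1 and 2.57 ± 0.201 in G2. TNFRSF12A was higher in G1 by 2.00 ± 0.134, and PCDH19 in G2 by 2.44 ± 0.205. In G1, DECR1, an enzyme of beta-oxidation, was lower at -1.90 ± 0.159 and TMSB15A at -1.97 ± 0.131. In G2, CTH was lower at -1.94 ± 0.185, ZCCHC12 at -1.78 ± 0.145, and the calcium-binding protein gene GCA was near background, at least 3.3-fold lower. Mitochondrial ribosomal proteins were lower in G2 in 28 of 71 cases and higher in 0 (32 and 0 adjusted over the list alone; median -0.25, camera adjusted p = 2.01e-08, adjusted p = 0.281 with an estimated correlation). Complex I subunits were lower in 15 of 37 cases in G2 (18 adjusted over the list alone; median -0.33, camera adjusted p = 4.48e-06, adjusted p = 0.304 with an estimated correlation) and in 9 in G1 (13, and 1 higher, adjusted over the list alone; median -0.23, or -0.142 after quantile normalization, camera adjusted p = 0.000387, adjusted p = 0.606 with an estimated correlation). Beta-oxidation genes were lower in 6 of 21 cases in G1 (9 adjusted over the list alone; median -0.29, camera adjusted p = 0.000273, adjusted p = 0.422 with an estimated correlation). Mitochondrial import genes were lower in 9 of 27 cases in G2 (10 adjusted over the list alone; median -0.26, camera adjusted p = 8.68e-05, adjusted p = 0.281 with an estimated correlation). All 8 lists called in G1 and all 10 called in G2 were lower than in G0, and 0 held with an estimated correlation. G1 differed from G0 in 2098 genes (998 higher, 1100 lower, 897 by at least 1.5-fold). G2 differed in 2410 (1160 higher, 1250 lower, 961 by at least 1.5-fold, a higher share of 48.1% as deposited and 38.4% after median centring), and in 1602 without G2 no Dox 2 and 1478 without G2 no Dox 3.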

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

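The splits of the arrays, and the test of mitochondrial line differences present without Dox, were chosen only after the result was seen. Every result in this part is a difference between lines in the effect of Dox. Each APOL1 form was profiled in its own line alone. An effect of the form can therefore not be told apart from other differences between the lines, such as the level of the insert. The splits exchange lines and cannot separate these either. The chip of each sample is not known, so a difference between chips stays open for each of these results.

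Dox changed genes more in G2 than in G0, by a median ratio of 1.3 over the genes called in 1 direction in all 3 APOL1 lines. Leaving out 1 array at a time gave ratios from 1.25, without G2 Dox 3, to 1.4, without G2 Dox 2, which argues against 1 array as the cause. Over the 951 genes whose Dox effect differed, a median share of 0.807 of the difference lay in the arrays labelled with Dox, or 0.193 if the Dox labels of the APOL1 lines were exchanged, so line differences already present without Dox stay open, and in 4 of the 8 called lists the larger part lay without Dox: the integrated stress response (mean -0.346 without and -0.00266 with Dox), glycolysis (-0.249 and 0.0494), S phase (-0.128 and 0.0174) and ribosome biogenesis (-0.254 and 0.186). A share of 0.174, or 165 of the 951, was still called against the G0 effect multiplied by 1.28, under the bound set for one response shared by both lines and larger in G2. The loss of a call does not show that such a response accounts for a gene, since that comparison has a larger standard error. Only 65.3% of the 951 had the sign of the G0 effect, and a larger shared response cannot account for the others. How many of these genes it accounts for is therefore not settled. A biological effect of the G2 form and a higher level of the insert in this line both stay open, since APOL1 was not detected. So does a difference between chips.

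Over 210 genes of 7 mitochondrial lists the Dox effect in the risk lines had a median difference from G0 of -0.0804, though 9 genes were called lower and 1 higher, and the medians of complex II to IV subunits (0.0164), ATP synthase (0.0482) and the TCA cycle (0.0454) were positive and changed sign with scaling. The median was -0.131 after quantile normalization and -0.0481 after median centring, at least 0.599 of the value as deposited, and between -0.135, without G2 Dox 2, and -0.0484, without G0 Dox 3, with 1 array left out. The genes go both ways (quartiles -0.222 and 0.0716), so the bounds set for these tests lie too near 0 to decide, and array scaling and 1 array stay open. The lines differed before induction: the median difference of the risk lines from G0 was -0.222 without Dox and -0.29 with Dox, a ratio of 0.765, or 1.31 with the Dox labels exchanged. Most of what separates the risk lines from G0 in these genes with Dox may therefore come with the lines rather than with induction, whichever way the labels run, and an effect of the APOL1 form on the rest stays open.

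The Dox effect differed from that of EV for 3603 genes in G0, 4227 in G1 and 5379 in G2. Exchanging line labels within each Dox state gave at most 1220, 1752 and 3210 genes in the other 99 of 100 splits. This argues against a chance split of these arrays as the source of the counts. Among the lists, the immediate early genes had medians of 1.27, 1.35 and 1.71, the integrated stress response -1.33, -0.915 and -0.893, the unfolded protein response -1.19, -0.77 and -1.04, and the histone genes 1.02, 0.879 and 1.01. Among the genes, FOS differed by a fitted 4.78 in G0 (its mean there without Dox was near background), by a fitted 5.04 in G1 (at least 4.85, since it was near background there without Dox) and by 5.15 in G2, EGR1 by 3.72 and 3.05 in G0 and G1, CXCL8 by 4.12 in G2, PCK2 by -3.20 in G0, INHBE by -3.06 and -3.00 in G0 and G1, TERF1 by -3.28 and -3.76 in G1 and G2, and GDF15 by a fitted -3.43 in G2, near background there with Dox (-2.95 or more in size). The other probe of TERF1 gave -0.189 and -0.275. The immediate early call held with an estimated correlation in all 3 lines, and those of the other 3 lists in G0 alone.

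Between G1 and G0 the effect differed for 178 genes, with at most 1 in the other splits, which argues against a chance split of these arrays. The list medians were 0.521 for the integrated stress response, 0.49 for the unfolded protein response, -0.166 for mitochondrial ribosomal proteins and 0.221 for aminoacyl-tRNA synthetases, and the last 3 lost their calls with an estimated correlation (adjusted p = 0.319, 0.78 and 0.725 with an estimated correlation). KPNA4 stood at 1.93, SLC6A9 at 1.74, HYOU1 at 1.60, TINF2 at -1.38 and ZNF784 at -1.29, and the fit gave -1.61 for ZNF365, near background in 3 of the 4 groups. TINF2 and ZNF784 lost their calls with no filter.

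Between G2 and G0 the effect differed for 951 genes, with at most 2 in the other splits, which argues against a chance split of these arrays. The list medians were 0.298 for cytosolic ribosomal proteins, 0.593 for ribosome biogenesis, 0.365 for the integrated stress response, 0.369 for immediate early genes, 0.32 for glycolysis, 0.258 for heat shock, 0.243 for the unfolded protein response and 0.207 for S phase. Of these 8 calls 1, that of ribosome biogenesis, held with an estimated correlation, and the median of the cytosolic ribosomal proteins was 0.0102 after quantile normalization. CCN1 stood at 1.60, CCDC86 at 1.55, GEM at 1.43, ZBTB42 at -1.60 and HOXB5 at -1.41, and the fit gave -1.57 for XYLT1, near background in 3 of the 4 groups.

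Between G2 and G1 the effect differed for 114 genes, with at most 1 in the other splits, which argues against a chance split of these arrays. TNFRSF12A stood at 1.65, DUSP1 at 1.23, KPNA4 at -1.91, SKIDA1 at -1.41 and NUPR1 at -1.38, and the fit gave 1.26 for ZNF365, near background in 3 of the 4 groups. The calls of DUSP1, NUPR1 and ZNF365 were lost in a fit to only the groups compared, among other settings.

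Between the risk forms and G0 the effect differed for 702 genes, with at most 185 in the other splits, which argues against a chance split of these arrays. The list medians were 0.403 for the integrated stress response, 0.444 for the unfolded protein response, 0.176 for cytosolic ribosomal proteins, 0.343 for ribosome biogenesis, -0.164 for mitochondrial ribosomal proteins, 0.251 for immediate early genes and 0.16 for aminoacyl-tRNA synthetases. None of these 7 calls held with an estimated correlation (adjusted p from 0.108 to 0.827), and the median of the cytosolic ribosomal proteins was 0.00331 after quantile normalization. ZCCHC12 stood at 1.40, HYOU1 at 1.36, CCDC86 at 1.25, CCN1 at 1.21, CTH at 1.15, KLF4 at 0.93, SLC3A2 at 0.86, PDIA4 at 0.83, ODC1 at 0.71, GARS1 at 0.56 and NCL at 0.52. ZCCHC12 and CTH were lower in G2 than in G0 without Dox, which enters their values. RNA28SN5 stood at -2.04, TMUB2 at -1.29, MRPS25 at -0.90 and MRPL10 at -0.81, and the fit gave -1.38 for XYLT1, near background in 5 of the 6 groups. RNA28SN5, TMUB2, MRPS25, MRPL10, PDIA4, GARS1 and NCL each lost the call under at least 1 setting, and other probes gave 0.438 for MRPL10 and 0.126 and -0.0452 for TMUB2. What these splits say of chance concerns the counts of genes, not single genes or lists. With 100 splits no share under 1 in 100 can be shown. The splits also treat the wells as separate experiments, which the labels do not state.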

How the results depend on the processing

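The stricter level filter, quantile normalization, median centring and exact 0 kept as 0 were chosen only after the data were seen, as was the use of the deposited values as the starting point. Of the alternatives planned for the scanner signals, no background correction, normexp with median centring, a stricter filter on detection p-values and the chip as a block were not run, because no label pairs those columns with samples. Array signal over background limits what can be tested: 11865 genes passed the level filter and 10141 the stricter one.

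Of 592 results for named genes, 422 were called, 352 of these under every alternative run for them, and 69 lost the call under at least 1. The minimum fold was applied to counts alone, and 573 of the 592 passed the stricter level filter. The call was lost in 47 cases without the filter, 17 with the mean of probes, 12 in a fit to only the groups compared, 10 each with quantile normalization and median centring, 6 with the replicate block and 3 with the trended and robust prior. Leaving out 1 array ended the call in 350 of 5784 pairs of a named result and an array, a total that includes results not called in the main fit. UQCR10 in G0 reversed with the mean of its probes, to -0.371, where the brightest probe gave 0.51 and the others -0.747 and -0.876, so its probes disagree. The 340 list tests include those not called in the main fit. Most list calls, 86 in all, were lost with an estimated correlation. For the Dox effects, the calls that held were 0 of 9 in EV, 5 of 7 in G0, 1 of 13 in G1 and 2 of 14 in G2. Against EV they were 4 of 11 in G0, 1 of 13 in G1 and 1 of 16 in G2. Against G0 they were 1 of 4 in G1, 1 of 8 in G2 and 0 of 7 for the risk forms. With the replicate block 2 calls were lost and 1 gained, and with fry 19 were lost and 70 gained. None of the lists called in a Dox effect of the APOL1 lines changed the sign of its median under rescaling. Median centring also turned the balance of higher and lower genes for Dox in G0 (47.6% higher to 54.1%) and in G1 (49.1% to 52.5%), for G2 and G0 against EV in the Dox effect (46.9% to 55.3% and 49.3% to 50.8%) and the reverse in G1 (50.7% to 48.7%), for G2 against G0 with Dox (43.7% to 50.3%) and for G0 against EV without Dox (49.0% to 57.0%).

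Without the filter the Dox effect differed between G1 and G0 for 37 genes, between G2 and G0 for 303, between G2 and G1 for 17 and between the risk forms and G0 for 136, and more genes were then tested and adjusted over. In a fit to only the groups compared, which estimates the spread from those groups' arrays alone, the counts were 1 for Dox in EV, 559 between G1 and G0, 474 between G2 and G0, 12 between G2 and G1, and 2902 between G2 and G0 with Dox. For G1 and G2 against G0 this reversed the order of the main fit, which called 178 and 951. The shared spread of the main fit includes G2 with Dox, the group with the largest median gene SD. Which of these differences involves more genes is therefore not settled. Between G2 and G1 the trended and robust prior gave 205, median centring 190 and the stricter level filter 181, and the cause was not tested. The replicate number as a block gave 69 genes between G2 and G1, all among the 114. Over all 24 arrays the numbers showed no pairing. Residuals of arrays with the same number in different groups correlated at a mean r of -0.0166, against 0.00838 for other pairs. Single pairs with the same number ran from r = -0.495 to 0.358, and no line was examined alone. A fold of at least 1.5 left by construction 2997 genes for Dox in G0, 3272 in G1 and 4471 in G2, 1393 and 2240 for G1 and G2 against G0 with Dox, 1503 for G0 against EV without Dox, and 897 and 961 for G1 and G2 against G0 without Dox.

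With 1 array left out, when fewer arrays estimate each group, the counts ran from 1 to 15 for Dox in EV, 4472 to 4785 in G0, 4825 to 5490 in G1 and 6233 to 7017 in G2. The Dox effect differed for 50 to 204 genes between G1 and G0, 334 to 1711 between G2 and G0, 21 to 567 between G2 and G1 and 128 to 1282 between the risk forms and G0, and the highest of the last 3 ranges came without G2 Dox 2. Without Dox, the count between G2 and G0 ran from 1478 to 1942.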

Other observations

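The splits of the arrays and the tests of Dox-free expression and of exchanged labels were chosen only after the result was seen, as were the comparisons of lines with Dox against EV.

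Other gene groups moved in both directions with Dox in the APOL1 lines, and camera called none of the following lists (adjusted p from 0.0593 to 0.988), though limma called single members. Of 25 genes of cell death, 6 rose and 4 fell in G0, 6 and 5 in G1, and 7 and 9 in G2, the same adjusted over the list alone. The survival gene BCL2 rose by 1.41, 1.61 and 1.13 (± 0.131), with 0.39, 0.466 and 0.407 at the least changed of its other probes. Of 27 autophagy genes, 9 rose and 5 fell in G0, 11 and 6 in G1, and 13 and 6 in G2 (9 and 5, 11 and 6, and 13 and 7 adjusted over the list alone), with ATG10 at -1.46, -1.34 and -1.90 (± 0.154). Of 26 lysosome genes, 11 rose and 2 fell in G0, 7 and 3 in G1, and 11 and 4 in G2 (12 and 3, 7 and 2, and 11 and 4 adjusted over the list alone), and the lysosomal enzyme GLA rose by 1.19, 1.34 and 1.99 (± 0.117). Of 22 p53 targets 6 rose and 3 fell in G0, 5 and 5 in G1, and 9 and 6 in G2, the same adjusted over the list alone. Of 18 NRF2 antioxidant genes 5 rose and 4 fell in G0, 7 and 5 in G1, and 9 and 5 in G2 (6 and 4 in G0 adjusted over the list alone, the others the same). Of 23 interferon-stimulated genes 9 fell in each line and 2, 2 and 3 rose, the same adjusted over the list alone, with SP110 at -1.71, -1.14 and -1.46 (± 0.139). Of 7 metallothionein and zinc genes 1, 2 and 3 rose and 2, 1 and 3 fell, the same adjusted over the list alone, with MT1F at -1.01, -1.07 and -1.59 (± 0.126). Of 31 G2 and M phase genes 9 rose and 3 fell in G0, 7 and 5 in G1, and 14 and 6 in G2 (9 and 3, 6 and 3, and 15 and 6 adjusted over the list alone).

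Of 20 cholesterol synthesis genes 4, 5 and 8 fell and 1, 2 and 2 rose in G0, G1 and G2 (4, 5 and 8, and 1, 1 and 2, adjusted over the list alone), with TM7SF2 at -1.38, -1.22 and -1.44 (± 0.165). Of 12 fatty acid synthesis genes 5 fell in each line and 2, 1 and 3 rose (6, 5 and 6, and 2, 1 and 3, adjusted over the list alone). With Dox, cholesterol genes were lower than in EV in 9, 13 and 11 of 20 cases, also adjusted over the list alone, with a list adjusted p = 0.376, 0.206 and 0.395 with an estimated correlation. Of 23 complex II to IV subunits 2, 2 and 5 rose and 1, 5 and 3 fell (2, 2 and 4, and 1, 3 and 2, adjusted over the list alone), of 16 ATP synthase subunits 0, 0 and 1 rose and 3, 4 and 4 fell (0, 0 and 1, and 2, 2 and 3, adjusted over the list alone), and of 18 TCA cycle genes 1, 4 and 7 rose and 1, 8 and 6 fell (1, 4 and 7, and 1, 9 and 6, adjusted over the list alone). The medians of the first of these lists in each line, and of the ATP synthase in G2, changed sign with the scaling of the arrays. Of 19 genes of mitochondrial dynamics and mitophagy 5, 4 and 6 rose and 5, 5 and 6 fell, the same adjusted over the list alone, with the mitophagy kinase PINK1 up by 0.78, 0.79 and 0.80 (± 0.118). Markers of other cells were not called as lists either, and their counts follow, with counts adjusted over the list alone in brackets where they differ. Of 7 podocyte and tubule genes 1, 5 and 1 rose and 0, 0 and 1 fell, of 8 fibroblast genes 1, 2 and 3 rose and 0, 1 and 1 fell, of 10 carcinoma epithelium genes 2, 3 and 2 rose and 3, 3 and 4 fell, and of 8 neuronal genes 3, 3 and 4 rose and 2, 0 and 1 fell (3 fell in G0), with the neurofilament gene NEFM up by 1.06, 1.61 and 2.16 (± 0.139). Of the leukocyte and endothelial markers 2 were measured: CD14 rose by 2.04, 2.02 and 2.17, and CD68 stood at -0.57, -0.52 and -0.60, where its other probes disagreed. Of the APOL family only 1 member was tested, and 0 of 13 mitochondrially encoded transcripts could be, so no list test was run for these 3 lists.

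The stress response genes stood high without Dox in the APOL1 lines and fell towards the EV level with Dox. The median change of the integrated stress response in G0 was -1.20 as deposited, -1.19 after quantile normalization and -1.15 after median centring, at least 0.959 of it, so neither rescaling removed the fall. The deposited arrays already had nearly equal means, and centring moved the G0 median of all genes only from -0.00314 to 0.0464. Rescaling could therefore change little, and an effect of the earlier, unstated scaling stays open. Expression of APOL1 without Dox could act as a weaker form of the induced state. It would then shift the uninduced G0 line from EV in the direction of the Dox effect. Across genes that difference correlated with the Dox effect in G1 at r = -0.234 and in G2 at -0.24. With the Dox labels of the APOL1 lines exchanged, r was -0.651 and -0.667. These values argue against such a weaker form as the whole cause. A shift shared by the uninduced lines is subtracted in the Dox effect and lowers r by itself. The test therefore cannot decide about low expression with an effect of another kind, which stays open. Labels with and without Dox exchanged in the APOL1 lines cannot be told apart from a real fall: in 53 stress genes the arrays labelled with Dox lay closer to EV in 3 of the 3 lines, in all genes in 0, and APOL1, which would decide, was not detected. A candidate explanation that stays open and untested is a difference in culture between the EV line and the other lines before induction.

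For groups of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For Dox in EV the real split gave 3 genes and the highest other 636, and 2 of the 10 gave at least 3. That highest split set EV no Dox 1, EV no Dox 3 and EV Dox 1 against the other arrays of the line. This structure does not follow Dox and follows the replicate number only in part. Both arrays numbered 1 were on the first side and both numbered 2 on the other, while those numbered 3 were divided. Whether the numbers pair arrays within the EV line was not tested. The real value and the highest other were 5298 and 0 for Dox in G0, 5690 and 0 in G1, 6934 and 0 in G2, 3207 and 1 for G1 against G0 with Dox, 4455 and 39 for G2 against G0 with Dox, 3218 and 1 for G0 against EV without Dox, 2098 and 0 for G1 against G0 without Dox and 2409 and 0 for G2 against G0 without Dox, on the 11864 genes with complete values.

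Genes with several kept probes gave a further check of direction. Other probes of called genes had the same direction in 83.9% of cases for Dox in G0, 82.9% in G1 and 81.6% in G2, in 72.0% for the difference between G1 and G0, 74.2% between G2 and G0, 83.3% between G2 and G1 and 68.8% between the risk forms and G0.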
